A study of Mus musculus with 10 samples.

How the data were processed

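Macrophages and microglia (resident and infiltrating phagocytes of the nervous system) were profiled by droplet single-cell RNA sequencing from mouse retina and optic nerve. The mice were 10 weeks old. Injured tissue had received an optic nerve crush, a standard lesion that severs retinal ganglion cell (RGC) axons, at 8 weeks, which was 2 weeks before collection. The study describes 10 samples in 4 groups. In the deposited table the 4 injured retina samples appear as 2 pools of 2 samples each, so that 8 libraries could be told apart, 2 per group. A library is the unit of replication here, and the table gives no way to separate the animals inside a pool.

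Per the labels, the authors aligned reads to the mm10 mouse genome with Cell Ranger 1.3 after bcl2fastq 2.17.1.14, removed cells with fewer than 200 or more than 6500 genes, and merged and normalised the data with Seurat 4.0.3 and harmony. The stated total of 1168 macrophages and microglia equalled the 1168 cells in the table, which held 205 to 6231 detected genes per cell. The deposited values were in 2 units. For the 209 retina cells the authors deposited raw counts of unique molecular identifiers (UMIs). For the 959 optic nerve cells the deposited values were ln values, the natural log of 1 plus 10000 times the UMI count divided by the cell's total. Each of the 1374534 optic nerve values above 0 gave a whole UMI count within a tolerance of 0.01 when the log was undone, so counts were recovered for all cells. A median of 96.6% of a cell's total UMIs lay in the genes kept for the optic nerve.

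The table had 52181 gene entries, of which 31394 of the 31833 with an Ensembl mouse identifier matched a symbol in GENCODE M21 (genome build GRCm38), and 16620 held a UMI. Uninjured retina held 0 UMIs in the last 24183 entries, whereas the other groups held some there. Uninjured retina therefore differed from the other groups in gene annotation or merging. This difference coincides with injury in the retina and with tissue among uninjured libraries. Whether the other groups shared the same annotation was not shown. Retina injury was tested only on the first 27998 entries. Joint fits used the 11904 genes with a UMI in both tissues. No doublet caller was run, and 2 barcodes each occurred in 2 cells.

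Injury in retina was tested with edgeR 4.0.16 quasi-likelihood on UMIs summed per library (TMM normalisation, filterByExpr, 4 libraries), which gives log2 fold changes. Injury in optic nerve, the interaction of injury and tissue, and both comparisons of tissues were tested with limma 3.58.1 (trend) on the mean ln value per library over all 8 libraries. Retina counts were first put on the optic nerve scale. Effects from limma are differences of mean ln values and not log2 fold changes. limma took the 5298 genes with a UMI in at least 10% of cells. That filter favours genes seen in injured optic nerve library 3, which held 682 of the 1168 cells. Rbpms-positive cells (at least 1 Rbpms UMI) were compared with Rbpms-negative cells by limma with the library as a block, in the 4 libraries with at least 5 cells of each class, and Rbpms itself was left out. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. Errors of effects are standard errors from the fit, and levels are CPM, the UMIs of a gene scaled to a common library total, with the SD over libraries.

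Gene lists, 15 programs and 23 cell types, were tested with camera at an inter-gene correlation of 0.01, and with the correlation estimated and with fry as alternatives. A list needed 5 measured genes, which left 16 lists in retina and 18 in the limma comparisons. The Rbpms share per library and the shares of cell classes were compared by an exact two-sided permutation test that reassigned injury within each tissue, with 36 assignments and a smallest possible p of 0.0556, or more where shares of 0 tie. Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5). A cluster was named when 2 markers of a cell-type list were among its 10 leading genes and 3 among its 50 leading genes. Cells with at least 5 of 14 endothelial markers were called endothelial-like. Intervals for shares, and for folds of genes with few UMIs in a retina group, come from exact Clopper-Pearson 95% intervals, a count of 0 was given the limit of 3 counts, and all of these cover counting error only.

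The genes named for each comparison were the 12 that rose and the 12 that fell with the smallest adjusted p and a mean log2 CPM of at least 5, without unnamed models, haemoglobin, mitochondrial and Xist genes. From each list, 2 to 4 members with the smallest p were named. Where no gene passed, the 5 genes with the smallest p were given as values. Members with 3 or fewer UMIs in a group were passed over where no ratio is given.

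The comparisons, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Several choices came later. First fits with edgeR and with limma, and the unfiltered limma fit with its alternatives, had been seen when the steps were settled. In tests on simulated data with 200 changed genes, limma on all 11904 genes recovered none of them, and the filter at 10% of cells, listed beforehand as an alternative, then replaced it. This raised the number of calls in each of the 5 limma comparisons, and the unfiltered counts are printed beside the filtered ones. With the filter, 62.5% of simulated 8-fold changes and 14.3% of 4-fold changes were recovered for injury in optic nerve, against 85.5% and 31.5% with edgeR in retina. The recovered shares of 8-fold changes were 21.3% for the interaction, 56.3% and 65.4% for uninjured and injured tissues, and 65.2% for the Rbpms classes. False calls made up 1.47% of calls in retina, 0% in optic nerve injury, 15.4% in the interaction, 10.5% between uninjured and 6% between injured tissues, and 2.78% between Rbpms classes. Each comparison was simulated once. Apart from the changed genes, all libraries shared the same mean profile, with no differences in tissue or cell type. The share for the interaction rests on 2 unchanged genes called. These shares are thus not error rates of the calls below.

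The plan had placed all 4 groups in one fit. Fitting retina on its own libraries, the first gene entries, the common ln scale, the numbers for naming clusters and endothelial-like cells, and the least list size were chosen after seeing the data. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, other filters on low counts (none, or 10 counts in 2 of 4 or 4 of 8 libraries), pseudocounts of 0.1 and 1 on unlogged means, a minimum of 30 cells, only the groups compared, and leaving out each library. After seeing the data, edgeR on recovered counts, fits without T-like, oligodendrocyte-like and endothelial-like cells, fits without genes that overlap another, genes with a UMI in both retina groups, cells thinned to 1000 UMIs, and these cells at full depth were added. No paired analysis was possible because the injured retina pools carry 2 sample numbers each. R 4.3.3 and Python 3.11.15 were used.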

Results

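Macrophages and microglia of mouse retina and optic nerve, with or without an optic nerve crush 2 weeks earlier, were measured in 1168 cells and 7920570 UMIs. Injured retina comprised 109 cells with 1420930 UMIs in the pool of samples 1 and 2, and 57 cells with 310892 UMIs in the pool of samples 3 and 4. Uninjured retina comprised 31 cells with 142787 UMIs in library 5 and 12 cells with 56838 UMIs in library 6. Injured optic nerve comprised 146 cells with 318715 UMIs in library 1 and 682 cells with 5234954 UMIs in library 3. Uninjured optic nerve comprised 103 cells with 351333 UMIs in library 2 and 28 cells with 84121 UMIs in library 4. The median depth per cell ran from 1078 UMIs in injured optic nerve library 1 to 12989 UMIs in the first injured retina pool, so the tissues differed in depth. The p-values of single genes and of shares below rest on the spread between libraries. These were all 8 libraries for shares and for limma on injury and tissue, and 4 for edgeR in retina. For the Rbpms classes they were the positive and negative cells of 4 libraries. For single genes, limma and edgeR estimate that spread partly from the other genes, and limma does so almost wholly for the Rbpms classes. The p-values from camera set the genes of a list against the other genes at a preset correlation, so they do not measure that spread alone.

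The series asks whether some microglia and macrophages carry Rbpms, an RNA-binding protein gene used as a marker of RGCs. Rbpms (ENSMUSG00000031586) is a protein-coding gene on the minus strand of chromosome 8 at 33782643 to 33929863 in GRCm38 and overlaps no other gene. The table held 106 Rbpms UMIs in 72 cells, or 6.16% of cells. Of these cells 57 (79.2%) had 1 UMI, and the highest count was 14. In uninjured retina 16.1% of cells in library 5 (5 of 31, 95% interval 5.45% to 33.7%) and 16.7% in library 6 (2 of 12, 2.09% to 48.4%) were positive. In injured retina 14.7% (16 of 109, 8.63% to 22.7%) were positive in the pool of samples 1 and 2, and 3.51% (2 of 57, 0.428% to 12.1%) in the pool of samples 3 and 4. In uninjured optic nerve 5.83% (6 of 103, 2.168% to 12.2%) and 7.14% (2 of 28, 0.877% to 23.5%) were positive in libraries 2 and 4. Injured optic nerve had 0.685% (1 of 146, 0.0173% to 3.76%) in library 1 and 5.57% (38 of 682, 3.97% to 7.57%) in library 3.

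**Figure D1:**
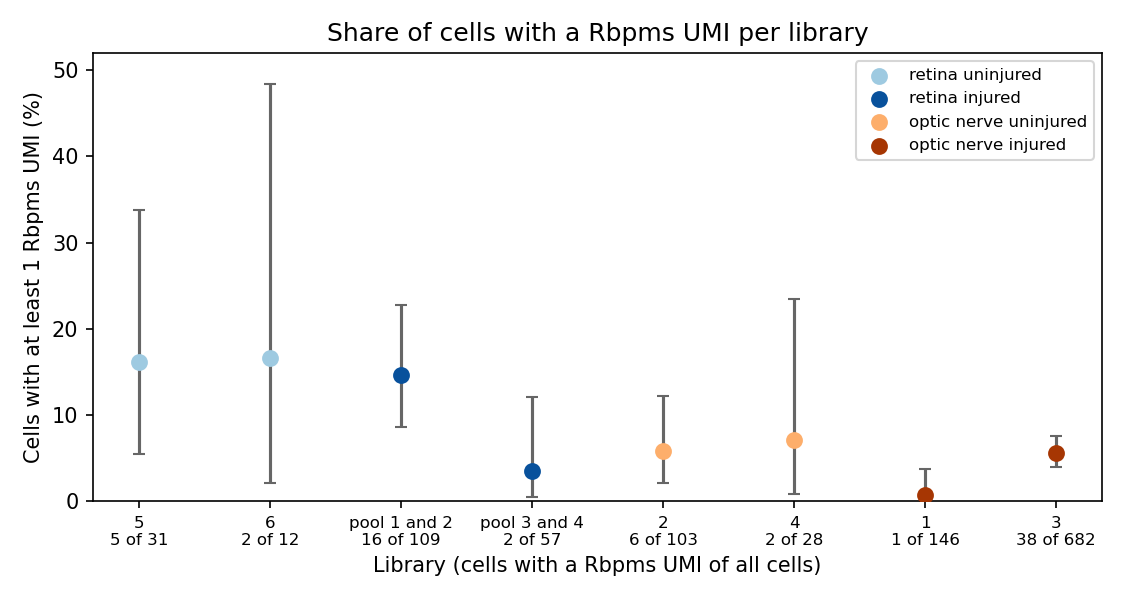
Percentage of cells with at least 1 Rbpms UMI (vertical axis) in each of the 8 libraries (horizontal axis), coloured by group, with points for the shares and bars for exact 95% intervals. The shares run from 0.685% in injured optic nerve library 1 to 16.7% in uninjured retina library 6, and the intervals of injured and uninjured libraries overlap within each tissue.

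The share of Rbpms-positive cells was lower by 5.33 percentage points in injured than in uninjured libraries, averaged over the 2 tissues (difference -5.33). The exact two-sided permutation test gave p = 0.0556, the smallest that 36 assignments allow, so no p under the threshold could be reached. The difference was -8.12 points without the injured retina pool 1 and 2, -2.54 points without pool 3 and 4, and -1.95 points (exact permutation p = 0.667) without T-like, oligodendrocyte-like and endothelial-like cells. With each cell thinned to 1000 UMIs, which left out 297 cells, the difference was -1.94 points (exact permutation p = 0.0556), with expected shares of 0.760% in injured and 3.36% in uninjured retina and 0.676% and 1.95% in optic nerve. Over summed UMIs of all cells Rbpms stood at a mean of 10.3 CPM in injured and 35.1 CPM in uninjured retina, and at 7.68 and 39.7 CPM in optic nerve. Uninjured optic nerve libraries 2 and 4 had 19.9 and 59.4 CPM from 7 and 5 UMIs. Injured optic nerve libraries 1 and 3 had 3.14 and 12.2 CPM. The thinned shares and these CPM include the T-like, oligodendrocyte-like and endothelial-like cells, and neither was computed without them.

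Rbpms was unevenly spread over cell classes. Of the 9 endothelial-like cells 6 (66.7%) were positive, and they held 27 Rbpms UMIs, 25.5% of the total, at 250 CPM and a median depth of 4652 UMIs. Border macrophage-like cells were positive in 7 of 82 (8.54%, 17.4 CPM, median depth 3783.5 UMIs). The remaining 947 myeloid cells were positive in 57 (6.02%, 9.71 CPM, median depth 2403 UMIs). Oligodendrocyte-like cells were positive in 2 of 83 (2.41%, 16.2 CPM, median depth 1638 UMIs). No T-like cell was positive (0 of 47, which allows a share of up to 6.38%, median depth 2422 UMIs). Per UMI, the remaining myeloid cells lay below and border macrophage-like cells close to the level in oligodendrocyte-like cells. The level in oligodendrocyte-like cells rests on 3 UMIs in 2 cells.

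Other RGC markers gave few UMIs. Slc17a6, Pou4f1, Pou4f2, Pou4f3, Isl1, Opn4 and Atoh7 had a UMI in 0 cells, although the transporter Slc17a6 and the Pou4f factors are standard RGC markers. Spp1, which phagocytes also express, had a UMI in 58.3% of Rbpms-positive and 58.7% of Rbpms-negative cells. Stmn2 was seen in 4.17% and 0.274%, and Thy1 in 0% and 1.92%. A marker other than Rbpms and Spp1 had a UMI in 9 of the 72 positive cells (12.5%) and 68 of the 1096 negative cells (6.20%). At least 2 other RGC markers were seen in 3 positive and 22 negative cells. Positive cells were deeper than negative cells, with medians of 14751.5 and 2159 UMIs.

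Rbpms-positive cells differed from Rbpms-negative cells of the same libraries in 2 of 5298 genes by limma. The nuclear long noncoding RNA Malat1 (chromosome 19, 5795690 to 5802672, overlapping another gene) rose by 0.85 ± 0.12 in mean ln value (limma adjusted p = 1.3e-08). The transcription regulator Tsc22d1 (chromosome 14, 76414961 to 76507765) rose by 0.52 ± 0.12 (limma adjusted p = 0.024). No gene fell, and the smallest p-values below 0 belonged to Gphn (-0.19 ± 0.053), Car2 (-0.19 ± 0.058), Msmo1 (-0.17 ± 0.065), Tor1aip2 (-0.14 ± 0.058) and the myelin-associated Gpm6b (-0.24 ± 0.097). Of the 16 measured homeostatic microglia genes none passed, with 11 above and 5 below 0, for example Jun at 0.30 ± 0.20, Cx3cr1 at 0.23 ± 0.19 and Fcrls at -0.14 ± 0.12. Of the RGC markers, Spp1 alone was seen in enough cells to be tested, and it did not pass (-0.26 ± 0.16).

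By camera, the oligodendrocyte list was lower (adjusted p = 0.0167), the chemokine list lower (adjusted p = 0.0214) and the heat shock list higher (adjusted p = 0.0238) in Rbpms-positive cells, each with adjusted p = 0.891 with an estimated correlation. No gene of these 3 lists passed, over all genes or adjusted over the list alone. Mbp stood at -0.38 ± 0.17, Ccl4 at -0.49 ± 0.20 and Hsp90ab1 at 0.40 ± 0.20. The median of the heat shock list turned from 0.20 with limma to -0.21 (log2) with edgeR, where the median over all genes was also below 0 (-0.12). The lists were not tested with negative cells matched on depth, although positive cells were deeper. None of the other 15 lists passed, at camera adjusted p-values from 0.0719 for mitochondrially encoded genes to 0.869 for border macrophages.

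Neither gene was called by limma once negative cells were matched on depth, where 0 genes passed (130 at an unadjusted p under the threshold) and both had an adjusted p of 0.86. With T-like, oligodendrocyte-like and endothelial-like cells also left out, the depth-matched limma fit called 3 genes, Malat1 among them. All fits without these cells rested on injured retina pool 1 and 2 and injured optic nerve library 3 alone. Uninjured retina library 5 and uninjured optic nerve library 2 then had 4 and 3 positive cells, too few to be used, so no uninjured library was included. limma also called 0 genes without the replicate block (53 unadjusted), and 0 of all genes with a UMI in both tissues (332 unadjusted). edgeR on recovered counts called 56 genes (39 up, 17 down) and DESeq2 13. On the log2 scale edgeR gave -0.13 for Malat1, 1.96 for Tsc22d1 (edgeR adjusted p = 4.2e-05) and -1.75 for Spp1 (edgeR adjusted p = 0.024). Without T-like, oligodendrocyte-like and endothelial-like cells Tsc22d1 stood at 0.11 (limma adjusted p = 0.86). With edgeR and depth matching it stood at 2.45 (edgeR adjusted p = 0.027). Leaving out any 1 of the injured retina pool 1 and 2, uninjured retina 5, uninjured optic nerve 2 or injured optic nerve 3 left 1 gene, Malat1.

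Cells other than microglia and macrophages were present. A T- and NK-like cluster of 47 cells, marked by Cd3d and Cd3e, made up 20.2% (22 of 109) and 42.1% (24 of 57) of the injured retina pools. It made up 0 of 31 and 0 of 12 cells of uninjured retina, which allow shares of up to 9.68% and 25%. An oligodendrocyte-like cluster, marked by Mal and Mag, was seen in optic nerve, at 8.22% and 6.16% of injured libraries 1 and 3 and 24.3% and 14.3% of uninjured libraries 2 and 4. A border macrophage-like cluster, marked by Mrc1, F13a1 and Stab1, made up 41.7% of uninjured optic nerve library 2 and 3.57% of library 4. It was 6.16% of injured optic nerve library 1, 3.67% of injured library 3 and 12.9% (4 of 31) of uninjured retina library 5.

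Averaged over tissues, the T-like share differed between injured and uninjured libraries by 15.6 points (exact permutation p = 0.167). The oligodendrocyte-like share differed by -6.05 points (exact permutation p = 0.333), the border macrophage-like share by -12.1 points (exact permutation p = 0.5) and the endothelial-like share by -2.93 points (exact permutation p = 0.167). Because shares of 0 tie, the smallest p that any assignment of these shares gives is 0.333 for oligodendrocyte-like cells and 0.167 for the other 3 classes. All but the border macrophage-like difference stood at that limit, so none of the 4 could pass. Without uninjured optic nerve library 2 the border macrophage-like difference was -2.55 points and the oligodendrocyte-like one -3.55 points, and without library 4 they were -21.6 and -8.54 points. Without library 4 the endothelial-like difference was -1.63 points.

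In injured against uninjured retina, microglial identity genes were lower and heat shock and ribosomal protein genes higher. Annotation or merging differed between these groups, so the changes below cannot be assigned to the crush alone. Olfml3 (chromosome 3, 103722222 to 103738001), a homeostatic microglia gene, fell from 953 ± 170 CPM in uninjured to 60.3 ± 16.7 CPM in injured retina (SD, n = 2 each), a log2 change of -3.86 ± 0.30. The lysophospholipid receptor Gpr34 (chromosome X, 13632089 to 13640858) fell from 1271 ± 93.7 to 148 ± 10.6 CPM, a log2 change of -3.09 ± 0.27. The co-chaperone Bag3 (chromosome 7, 128523616 to 128546981) rose from 68.4 ± 22.1 to 691 ± 124 CPM, a log2 change of 3.20 ± 0.36. The ribosomal protein gene Rps15 (chromosome 10, 80292453 to 80294114) rose from 172 ± 44.1 to 2208 ± 310 CPM, a log2 change of 3.61 ± 0.34. The inflammatory cytokine gene Tnf fell from 1285 ± 24.3 to 141 ± 49.1 CPM, a log2 change of -3.11 ± 0.31.

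**Figure D2:**
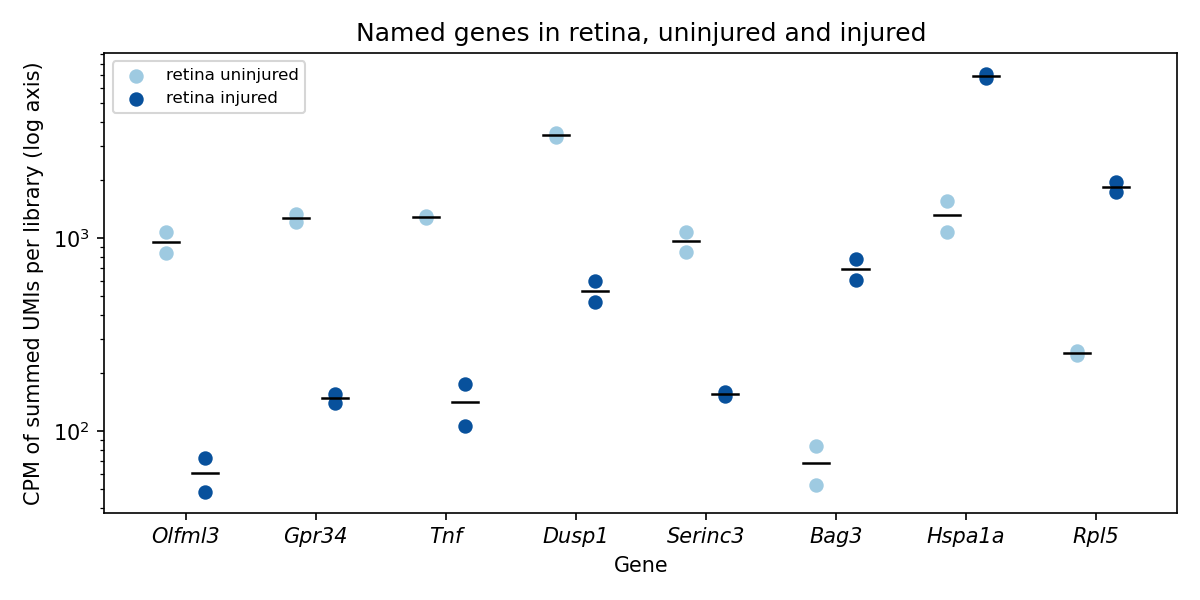
CPM of summed UMIs (log axis) of 8 genes in the 2 uninjured and 2 injured retina libraries, with 1 point per library and a line at the group mean. Olfml3, Gpr34, Tnf, Dusp1 and Serinc3 are lower and Bag3, Hspa1a and Rpl5 higher in both injured pools than in both uninjured libraries.

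Among the genes with the smallest adjusted p that rose were further ribosomal protein genes, namely Rpl17 (3.08), Rpl23a (2.97), Rpl5 (2.85), Rpl13a (2.58) and Rps25 (2.36, all log2). Among those that fell were Tcim (-5.82), Ptp4a1 (-5.44), the kinase gene Sgk1 (-2.93), Anxa3 (-2.69), the phosphatase gene Dusp1 (-2.67), Serinc3 (-2.60) and the lysosomal enzyme gene Hexa (-2.39). Other named genes rested on few UMIs in 1 group, and their intervals cover counting error of UMIs summed per group and not the spread between libraries. The B-cell chemokine Cxcl13 had 0 UMIs in uninjured retina and was at least 85.3-fold higher in injured retina against a floor of 3 UMIs over the group, and Nme2 at least 28.8-fold higher. Gdpd3 was higher 56.8-fold (interval 15.7 to 469), the proton pump subunit Atp6v0c 36.8-fold (12.5 to 179) and the fibronectin gene Fn1 82.6-fold (14.8 to 3269). The microglia gene Fcrls, with 1 UMI in injured retina, was lower 616-fold (107 to 24667), and the pseudogene Rpl27-ps3 at least 54.9-fold lower.

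Of 20 measured homeostatic microglia genes 13 fell and none rose (18 fell adjusted over the list alone), with Fcrls, Olfml3 and Gpr34 in the lead (camera adjusted p = 1.1e-11, adjusted p = 0.293 with an estimated correlation). Of 19 immediate early genes, fast transcriptional responders, 16 fell and none rose (18 adjusted over the list alone), among them Dusp1 at -2.67, Fos at -2.33, Ier2 at -2.28 and Junb at -2.14 (camera adjusted p = 1.1e-11, adjusted p = 0.293 with an estimated correlation). Of 13 chemokine and cytokine genes 9 fell and 1 rose (the same counts adjusted over the list alone). Tnf, Il1a (-1.88), Ccl4 (-1.81) and Ccl3 (-2.12) fell, and Ccl5, which T cells also make, rose by 2.93 (camera adjusted p = 0.0019, adjusted p = 0.537 with an estimated correlation). Of 22 lysosome and phagocytosis genes 6 fell (9 adjusted over the list alone), such as Hexa and Cd68 at -1.38 (camera adjusted p = 0.0026, adjusted p = 0.569 with an estimated correlation). Of 9 complement genes C5ar1 (-2.52) and Itgam (-1.55) fell (3 fell and 1 rose adjusted over the list alone), both receptor genes (camera adjusted p = 0.0050, adjusted p = 0.344 with an estimated correlation).

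Of 12 heat shock genes 9 rose and none fell (10 adjusted over the list alone), with Bag3, Hspa1b at 3.13, Hsp90aa1 at 2.31 and Hspa1a at 2.38 (camera adjusted p = 6.1e-07, adjusted p = 0.293 with an estimated correlation). Of 29 ribosomal protein genes 20 rose and none fell (25 adjusted over the list alone), such as Rpl5 and Rplp2 at 2.67 (camera adjusted p = 1.1e-11, adjusted p = 0.537 with an estimated correlation). The disease-associated microglia list, genes of an activated state, did not pass as a group (camera adjusted p = 0.0858). Of its 21 measured genes 7 fell, such as Cd9 (-2.21), Timp2 (-1.88) and Trem2 (-1.47), and B2m rose by 1.09. Nor did the lists pass by camera for class II (adjusted p = 0.119) and class I antigen presentation (0.839), interferon response (0.959), lipid handling (0.107), glycolysis (0.158), oxidative phosphorylation (0.107), mitochondrially encoded genes (0.906) and Muller glia (0.786). Single members that changed included Abca1 (2.07), Cox4i1 (1.12), Ndufa4 (-1.12), mt-Nd1 (1.17), H2-Q7 (1.33) and Bst2 (-1.57). The T-like cells described above, 20.2% and 42.1% of the injured pools, moved with these groups.

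In all, edgeR called 653 of 3312 genes in retina, 331 up and 322 down, and 531 of these were also called without T-like, oligodendrocyte-like and endothelial-like cells (580 calls). Genes that overlap another made up 13.3% of called and 8.35% of other genes, and Rpl23a, Rpl5, Nme2, Rpl13a, Ptp4a1 and Anxa3 were among them. The median log2 change of all tested genes was 0.0686. On all 8 libraries edgeR called 260 genes (156 up, 104 down) and limma 899 (623 up, 276 down). The DESeq2 Wald test on the retina libraries called 341, and 428 and 415 were called without injured pool 1 and 2 and without pool 3 and 4. Because annotation or merging differed between the retina groups, genes such as Cxcl13, Fcrls, Nme2 and Rpl27-ps3 may not have been countable in both groups.

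In optic nerve, genes of the disease-associated microglia program rose after crush. The lipid carrier Apoe (chromosome 7, 19696109 to 19699188) rose from 18399 ± 4129 CPM in uninjured to 79744 ± 25870 CPM in injured nerve (SD, n = 2 each), by 3.09 ± 0.38 in mean ln value. The lysosomal protease Ctsd (chromosome 7, 142375911 to 142388038, overlapping another gene) rose from 1738 ± 648 to 10423 ± 6290 CPM (1.90 ± 0.29). The Trem2 adaptor Tyrobp rose from 1288 ± 454 to 4074 ± 1679 CPM (1.52 ± 0.27), and the apolipoprotein Apoc1 from 20.5 ± 4.76 to 2139 ± 2534 CPM (1.501 ± 0.289). The transcription factor Jun (chromosome 4, 95049034 to 95052222) fell from 3081 ± 19.0 to 677 ± 96.3 CPM (-1.35 ± 0.22). The mRNA-decay factor Zfp36 fell from 2084 ± 479 to 489 ± 57.6 CPM (-1.47 ± 0.27).

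**Figure D3:**
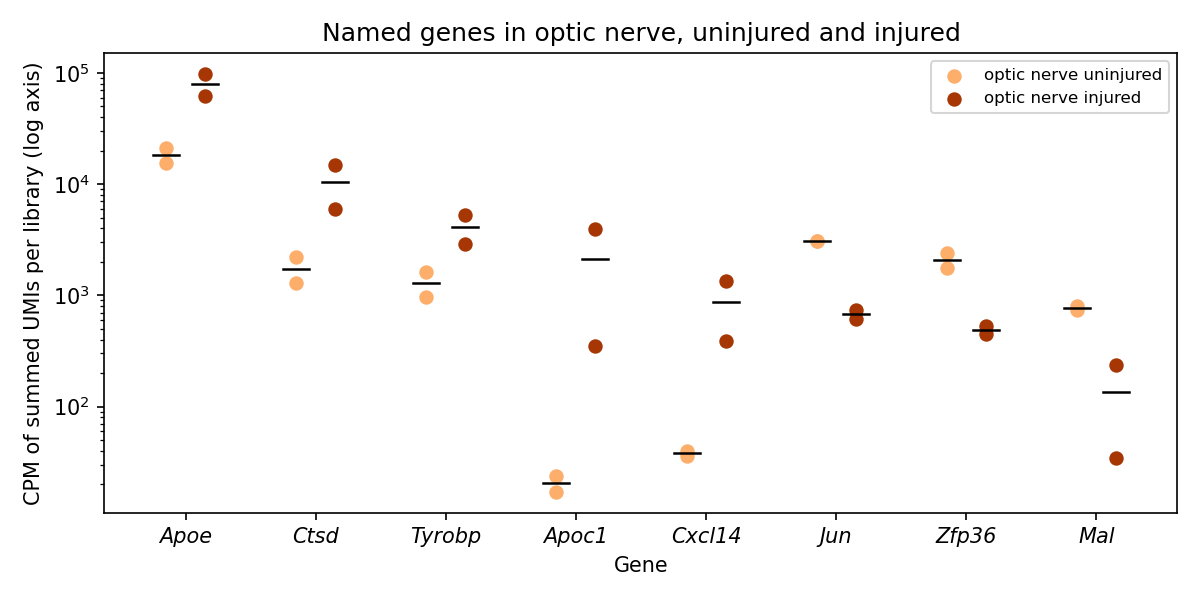
CPM of summed UMIs (log axis) of 8 genes in the 2 uninjured and 2 injured optic nerve libraries, with 1 point per library and a line at the group mean. Apoe, Ctsd, Tyrobp, Apoc1 and Cxcl14 are higher and Jun, Zfp36 and Mal lower in both injured than in both uninjured libraries.

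The other named genes that rose were Tmsb4x (0.93), the chemokine Cxcl14 (1.27), the ferritin gene Ftl1 (1.57), Rpl41 (0.99), the integrin Itgax (0.42), Fau (0.84), Eef1a1 (0.72) and the complement gene C1qa (0.98, all in mean ln value). Those that fell were the glial genes Gpm6b (-0.64) and Mal (-0.52), Clec2d (-0.42) and Malat1 (-1.68). With edgeR on recovered counts Ctsd, Cxcl14, Itgax, Apoc1, Jun and Zfp36 passed, whereas Apoe (log2 change 2.33, edgeR adjusted p = 0.062) and Tyrobp (1.87, edgeR adjusted p = 0.064) did not.

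Of 26 disease-associated microglia genes 9 rose and none fell (21 rose adjusted over the list alone), with Apoe, Ctsd, Tyrobp and Itgax in the lead (camera adjusted p = 1.6e-36, adjusted p = 0.0973 with an estimated correlation). A cluster led by Gpnmb, Apoc1, Lyz2 and Spp1 made up 28.6% of injured library 3, 1.37% of injured library 1, and 1.94% and 0% of uninjured libraries 2 and 4. Of 12 lipid handling genes Apoe, Apoc1 and Lpl (0.80) rose (8 adjusted over the list alone, camera adjusted p = 3.6e-17, adjusted p = 0.124 with an estimated correlation). Of 23 lysosome genes Ctsd, Ctss (1.302) and Ctsb (1.40) rose (10 adjusted over the list alone, camera adjusted p = 5.9e-09, adjusted p = 0.288 with an estimated correlation). Of 29 ribosomal protein genes Rpl41 rose (12 adjusted over the list alone, camera adjusted p = 4.7e-22, adjusted p = 0.0973 with an estimated correlation). Glycolysis genes (15), oxidative phosphorylation genes (22) and class I antigen presentation genes (10) were higher as groups with no gene called, with camera adjusted p of 1.2e-05, 0.0072 and 0.027 (adjusted p = 0.298, 0.607 and 0.170 with an estimated correlation).

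Of 10 mitochondrially encoded genes 5 fell (10 adjusted over the list alone), such as mt-Nd1 at -1.66 and mt-Co1 at -1.26 (camera adjusted p = 5.8e-18, adjusted p = 0.124 with an estimated correlation). The median of these 10 genes was -1.13 in mean ln value, and -0.32 on the log2 scale with edgeR on summed UMIs. A cluster of cells with a median of 956 UMIs made up 66.4% and 48.5% of injured libraries 1 and 3 and 12.6% and 28.6% of uninjured libraries 2 and 4. Of 19 immediate early genes Jun and Zfp36 fell (7 adjusted over the list alone, camera adjusted p = 1.2e-10, adjusted p = 0.0973 with an estimated correlation). The homeostatic microglia list was lower (camera adjusted p = 0.00034, adjusted p = 0.288 with an estimated correlation), yet the 1 of its 16 genes that fell was Jun, an immediate early gene, and P2ry12 stood at -0.62 ± 0.23. Of 5 myelin genes Mal fell (3 adjusted over the list alone, camera adjusted p = 6.9e-07, adjusted p = 0.150 with an estimated correlation), and Mbp stood at -1.19 ± 0.30. The oligodendrocyte-like cluster made up 24.3% and 14.3% of uninjured and 8.22% and 6.16% of injured libraries, and thus moved with this group. The camera test did not pass for complement (adjusted p = 0.109), in which C1qa and C1qb rose, nor for heat shock (0.342), class II antigen presentation (0.719), interferon response (0.0585), chemokines (0.466), border macrophages (0.161) and Muller glia (0.719).

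In all, limma called 30 of 5298 genes for injury in optic nerve, 19 up and 11 down, and 1 of all 11904 genes with a UMI in both tissues. edgeR called 53 (10 shared), edgeR without T-like, oligodendrocyte-like and endothelial-like cells 16, and limma without these cells 34 (22 shared). limma called 67 genes without injured library 1, 13 without injured library 3, 7 without uninjured library 2, and 1 with each cell thinned to 1000 UMIs.

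The interaction test asked whether injury changed genes differently in the 2 tissues, as the optic nerve effect minus the retina effect. Complement and lysosomal genes had higher effects in optic nerve, where C1qa (chromosome 4, 136895917 to 136898803) differed by 2.48 ± 0.29 and Ctsd by 3.43 ± 0.41. C1qa went from 4542 ± 1258 to 7084 ± 1443 CPM with injury in optic nerve and from 8161 ± 46.4 to 5764 ± 118 CPM in retina (SD, n = 2 each). Heat shock genes had higher effects in retina, where Hspa1b (chromosome 17, 34956436 to 34959238) differed by -3.42 ± 0.32 and Hspa1a by -3.22 ± 0.36. Hspa1b went from 624 ± 335 to 5778 ± 661 CPM in retina and from 1237 ± 416 to 3.15 and 21.5 CPM in the 2 injured libraries of optic nerve.

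Other named genes with a higher effect in optic nerve were Tmsb4x (1.53), C1qb (2.61), C1qc (2.49), Ftl1 (2.68), Tyrobp (2.76), Olfml3 (1.77), Cst3 (2.81), Ctsz (2.52), Gpr34 (1.95) and Actb (1.39). Of these, Olfml3, Gpr34, Cst3 and Actb fell in retina and changed little in optic nerve by CPM. Olfml3 went from 953 to 60.3 CPM with injury in retina and from 151 to 166 CPM in optic nerve. Cst3 went from 34582 to 11282 CPM and from 15935 to 15490 CPM. The rest fell in retina and rose in optic nerve. Named genes with a higher effect in retina were Atp6v0c (-1.35), Bag3 (-0.96), Arid5b (-0.996), Tnrc6b (-0.98), Rpl17 (-2.169), Pik3ap1 (-0.60), Slc38a2 (-1.29), Tagap1 (-0.77), S100a10 (-0.81) and Rps15 (-2.10). The interaction holds the retina contrast, in which annotation or merging differed between the groups, and Atp6v0c had 3 UMIs in uninjured retina.

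By list, the counts of genes whose effect was higher in optic nerve were 10 of 26 for disease-associated microglia (18 adjusted over the list alone), 9 of 23 for lysosome (12), 5 of 16 for homeostatic microglia (6), 3 of 19 for immediate early genes (7), 3 of 13 for chemokines (4) and 1 of 12 for lipid handling (2). Examples were Cd9 (2.63 ± 0.43), Trem2 (2.41 ± 0.42), Cd68 (1.81 ± 0.32), Fcrls (1.08 ± 0.19), Ier2 (1.42 ± 0.35) and Tnf (1.44 ± 0.26). Of 9 complement genes C1qa, C1qb and C1qc differed upward and C4b downward (-0.80 ± 0.20). The counts of genes whose effect was higher in retina were 6 of 11 for heat shock (8 adjusted over the list alone), 4 of 10 mitochondrially encoded genes (7), 3 of 29 ribosomal protein genes (5), 2 of 7 class II genes (4) and 1 of 5 myelin genes (3). The median of the mitochondrially encoded genes was -1.20 in mean ln value and -0.18 on the log2 scale with edgeR. Among the genes were mt-Nd1 (-2.27 ± 0.40), Rpl5 (-1.58 ± 0.36), H2-Aa (-1.41 ± 0.29) and Mal (-0.50 ± 0.13, but 2.73 on the log2 scale with edgeR).

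These 12 lists, and those for glycolysis (15 genes) and oxidative phosphorylation (22 genes) with no gene called, passed with camera adjusted p-values from 3.8e-18 for disease-associated microglia to 0.0195 for class II and myelin genes, and none passed with an estimated correlation (smallest adjusted p = 0.217 with an estimated correlation). The lists for border macrophages (camera adjusted p = 0.294), class I genes (0.260), interferon response (0.533) and Muller glia (0.919) did not pass. The T-like cells of the injured retina pools and the oligodendrocyte-like cells of optic nerve moved with these groups.

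In all, limma called 297 of 5298 genes for the interaction (90 up, 207 down), and 28 of all genes with a UMI in both tissues. edgeR called 72 (58 shared), DESeq2 112, limma without T-like, oligodendrocyte-like and endothelial-like cells 182 (140 shared), and limma on thinned cells 31. Without 1 library, limma called 157 and 106 genes (injured retina pools 1 and 2, and 3 and 4), 541 (uninjured retina 5), 165 and 86 (injured optic nerve 1 and 3), and 154 and 118 (uninjured optic nerve 2 and 4).

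Between uninjured tissues, myelin genes were higher in optic nerve and immediate early, chemokine and microglia genes were higher in retina. Mbp (chromosome 18, 82475146 to 82585637), a myelin protein gene, had 3226 ± 528 CPM in optic nerve and 8.80 ± 12.4 CPM in retina (SD, n = 2 each), a difference of 3.24 ± 0.30 in mean ln value. The chemokine Ccl3 (chromosome 11, 83647844 to 83649355) had 1165 ± 365 CPM in optic nerve and 8360 ± 2716 CPM in retina (-3.08 ± 0.29). Jun had 3081 ± 19.0 CPM in optic nerve and 9426 ± 554 CPM in retina (-2.10 ± 0.22).

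Other named genes that were higher in optic nerve were S100b (0.75), Mal (0.77), Gpm6b (0.92), S100a6 (0.53), the complement gene C4b (0.87), Car2 (0.61), Slc1a3 (1.15), Csrp1 (0.42), Ahnak (0.72) and Scd2 (0.65), several of them glial genes. Lower ones included Tmsb4x (-1.09), H3f3b (-2.07), Junb (-2.01), Tnf (-1.73), Actb (-1.47), Sgk1 (-2.29), Ubb (-2.06), Tagap (-1.02) and Herpud1 (-1.69).

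Lower in optic nerve were 17 of 19 immediate early genes (18 adjusted over the list alone), such as Egr1 (-2.29), and 12 of 16 homeostatic microglia genes (12), such as Olfml3 (-1.56), Gpr34 (-1.80) and Cx3cr1 (-1.93). The same held for 6 of 13 chemokines (7), 7 of 23 lysosome genes (10), 4 of 10 class I genes (6), such as H2-K1 (-1.29), and 3 of 11 heat shock genes (5), such as Hspa5 (-1.68). Of 9 complement genes C1qa, C1qb, C1qc, Itgam, C3ar1 and C5ar1 were lower and C4b was higher. Of 26 disease-associated microglia genes 8 were lower, such as Tyrobp (-1.56), and Apoe was higher (1.57 ± 0.38). Higher in optic nerve were all 5 measured myelin genes, 3 of 10 mitochondrially encoded genes (7 adjusted over the list alone), such as mt-Co3 (1.46), and Slc1a3, Apoe and Vim of 5 Muller glia genes. These lists, and oxidative phosphorylation as lower with 0 of 22 genes called, passed by camera with adjusted p-values from 6.7e-19 to 0.049, and none passed with an estimated correlation (smallest adjusted p = 0.0913 with an estimated correlation). Border macrophage, class II, interferon, lipid, glycolysis and ribosomal protein lists did not pass by camera (adjusted p = 0.175, 0.318, 0.434, 0.178, 0.414 and 0.0986). Mbp had a UMI in 62.5% of the 947 myeloid cells outside named clusters, as well as in 89.2% of oligodendrocyte-like cells, and moved with tissue alongside the myelin group. Oligodendrocyte-like cells (24.3% and 14.3% of uninjured optic nerve libraries 2 and 4, against 0% and 0% of uninjured retina libraries 5 and 6) also moved with these groups, the lower microglia genes among them. Border macrophage-like cells made up 41.7% and 3.57% of these optic nerve libraries and 12.9% and 0% of these retina libraries, so only optic nerve library 2 stood apart.

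In all, limma called 531 of 5298 genes between uninjured tissues, 94 up and 437 down, and 365 of all genes with a UMI in both tissues. On unlogged means with a pseudocount of 0.1 it called 483, of which 315 were up and 168 down, so the balance of directions depended on the scale. edgeR called 120 (89 shared), limma on the groups compared 260, and limma on thinned cells 102. Without uninjured retina library 5 or 6 limma called 907 and 351, and without uninjured optic nerve library 2 or 4 it called 227 and 242. Uninjured retina had 0 UMIs in the last 24183 gene entries, where uninjured optic nerve libraries 2 and 4 had 1313 and 332, so annotation or merging differed between these groups as well and was not separated from tissue.

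Between injured tissues, heat shock genes were lower and lipid and lysosomal genes higher in optic nerve. Hspa1b had 3.15 and 21.5 CPM in the 2 injured optic nerve libraries and 5778 ± 661 CPM in injured retina (SD, n = 2), a difference of -3.38 ± 0.23 in mean ln value. Apoe had 79744 ± 25870 CPM in optic nerve and 18862 ± 5899 CPM in retina (SD, n = 2 each, 2.63 ± 0.38), and Ctsd 10423 ± 6290 and 2263 ± 172 CPM (1.91 ± 0.29).

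Further named genes that were higher in optic nerve were Mbp (1.77), the endotoxin co-receptor Cd14 (1.58), Tmsb4x (0.45), Cxcl14 (1.02), the protease Ctsb (1.47), Apoc1 (1.38), Hexa (1.21), the lipase Lpl (0.74) and Tyrobp (1.199). Those that were lower were Hspa1a (-3.33), Atp6v0c (-1.40), Bag3 (-1.12), Hsph1 (-1.56), Dnajb1 (-1.85), Jun (-1.93), Hsp90aa1 (-2.42), Ndfip1 (-0.76), Timm23 (-0.45), Cd300lf (-0.62) and Cdk8 (-0.82).

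Lower in optic nerve were all 11 measured heat shock genes, 21 of 29 ribosomal protein genes (29 adjusted over the list alone), such as Rps29 (-0.66), Rps27 (-1.13) and Rpl5 (-1.21), 10 of 19 immediate early genes (13), such as Jund (-1.37), and 4 of 7 class II genes (6), such as H2-Aa (-0.97). Higher were 15 of 26 disease-associated microglia genes (18), with B2m lower, and 4 of 23 lysosome genes (6), with Mertk lower. Apoe, Apoc1 and Lpl of 12 lipid genes (4), 2 of 5 myelin genes (4), among them Mbp, and Apoe of 5 Muller glia genes (2) were also higher. Of 9 complement genes C1qa, C1qb and C1qc were higher. The complement list had a median effect of -0.0848 and a mean of 0.222 and was higher by camera, so these differ in sign. Glycolysis, with Hif1a lower, and border macrophage genes, none called, passed as higher. Adjusted p-values of these 12 lists by camera ran from 1.6e-33 to 0.0061, and none passed with an estimated correlation (smallest adjusted p = 0.0888 with an estimated correlation). Lists of homeostatic microglia (camera adjusted p = 0.767), class I (0.101), interferon (0.780), chemokine (0.0518), oxidative phosphorylation (0.144) and mitochondrially encoded genes (0.301) did not pass. T-like cells in the injured retina pools and oligodendrocyte-like cells in the optic nerve moved with these groups. Injured retina stood apart from the other groups for some genes. Atp6v0c had 545 CPM in injured retina, 10.5 in uninjured retina, and 10.4 and 1.43 in injured and uninjured optic nerve. Timm23 had 85.2, 3.50, 3.55 and 4.29 CPM in the same order, and Rpl13a 2198, 365, 251 and 488. A difference in annotation or merging between injured retina and injured optic nerve was not tested.

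In all, limma called 713 of 5298 genes between injured tissues, 40 up and 673 down, and 440 of all genes with a UMI in both tissues. The median effect of all genes was -0.0971, and -0.0032 with each cell thinned to 1000 UMIs, where 26 genes were called (25 shared). edgeR called 383 (193 up, 190 down) and limma on the groups compared 1168. Without 1 library, limma called 197 and 290 genes (injured retina pools 1 and 2, and 3 and 4), 1085 (uninjured retina 5), and 220 and 143 (injured optic nerve 1 and 3).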

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

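All tests of explanations here were chosen after the results were seen. Results stand here because the effect of injury differed between retina and optic nerve by a test of that difference, or because UMIs appeared in a sequence that no comparison used. By the interaction test the injury effect differed between tissues in 297 genes with limma and in 14 gene lists with camera. No list passed with an estimated correlation or with fry. Complement, lysosomal and microglia genes and others had a higher effect in optic nerve, namely Tmsb4x (1.53), C1qa (2.48), Ctsd (3.43), C1qb (2.61), Ftl1 (2.68), Tyrobp (2.76), C1qc (2.49), Olfml3 (1.77), Cst3 (2.81), Ctsz (2.52), Gpr34 (1.95) and Actb (1.39). For Olfml3, Gpr34, Cst3 and Actb this rested mainly on a fall in retina, since their CPM changed little in optic nerve. Heat shock genes and others had a higher effect in retina, namely Hspa1b (-3.42), Hspa1a (-3.22), Atp6v0c (-1.35), Bag3 (-0.96), Arid5b (-0.996), Tnrc6b (-0.98), Rpl17 (-2.169), Pik3ap1 (-0.60), Slc38a2 (-1.29), Tagap1 (-0.77), S100a10 (-0.81) and Rps15 (-2.10). The retina side of this test carries the same difference in annotation or merging as the retina comparison. An entry named Tceb2wpre, outside the mouse gene annotation, had 2 UMIs in 2 cells of the injured retina pool 1 and 2, both Rbpms-negative, and mCherry had 0 UMIs in all libraries.

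Rbpms UMIs in myeloid cells were few, and 3 sources were weighed. If every cell of a library held Rbpms at an equal share of its UMIs, 72.7 cells outside the endothelial-like class would hold a Rbpms UMI (95% range 68 to 77), against 66 seen, and 52 of 10000 draws were as low. The count also lay narrowly below the range without oligodendrocyte-like and T-like cells (64 against 65 to 74, 189 of 10000 draws as low) and with endothelial-like cells taken more widely (64 against 65 to 74, 109 of 10000 draws), which argues against an even background alone. These sets share most of their cells, so they are not separate tests. RNA of endothelial-like cells as the source would bring 863 UMIs of the endothelial gene Cldn5 to the other cells, where 1 was found. Cldn5 is itself a marker that defines that class, and the ratio rests on 9 cells with 27 Rbpms UMIs. Flt1, another such marker, had 72 UMIs in endothelial-like cells and 405 in the 947 remaining myeloid cells. Vwf and Pecam1 had 241 and 80 UMIs against 13 and 7, and Selp, which did not define the class, 542 against 1. RNA of RGCs was not tested and stays open, as does expression by the myeloid cells themselves.

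The genes that changed in injured retina, such as Olfml3, Gpr34 and Bag3, were weighed against 2 technical causes. With T-like, oligodendrocyte-like and endothelial-like cells left out, 531 of the 653 calls were shared, so T-like cells were not the whole cause. Different gene models or processing of injured and uninjured retina libraries cannot be told apart from injury, since 0 retina groups held libraries of both kinds. Ribosomal protein genes, Atp6v0c, Nme2, Cxcl13 and Fcrls may owe their change to this, and an effect of the crush stays open as well.

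Over all genes the median effect was below 0 in injured optic nerve against injured retina (-0.0971), and 94.4% of the 713 calls, Hspa1b among them, were lower. Thinning to 1000 UMIs left out 297 of 1168 cells, 67 and 201 of them in injured optic nerve libraries 1 and 3. In the other cells the median effect was -0.0519 at full depth and -0.0032 after thinning, so a difference in depth between the tissues may account for the shift of all genes, through the shallow cells and the depth of the others. The calls fell from 713 to 182 without the shallow cells and to 26 after thinning, and how far depth accounts for them stays open. Of the 713 genes 93.1% were still below 0 after thinning, with a median effect of -0.172 against -0.342 in the same cells at full depth. With edgeR 94.0% of the 701 of them that were measured were below 0, whereas 49.6% of its own calls were lower. A biological difference between tissues stays open as well, as does a difference in annotation or merging between these libraries.

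For the 2 genes called between Rbpms-positive and Rbpms-negative cells, Malat1 and Tsc22d1, 1 of the 8 splits of the libraries gave as many genes, the real one, and the highest other split gave 1. With 8 splits no share under 0.05 can be reached.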

How the results depend on the processing

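Fits with edgeR and TMM on recovered counts, retina fits on all 8 libraries, and fits without T-like, oligodendrocyte-like and endothelial-like cells, without overlapping genes, on thinned cells and on cells with at least 1000 UMIs were chosen after the results were seen. The difference of Rbpms-positive shares, averaged over tissues, kept its direction in all alternatives (-8.12 to -2.54 points without 1 library, -0.0809 points at 2 or more UMIs, -1.94 points on thinned cells, -28.4 as CPM, -4.92 points without cells with 2 or more other RGC markers), as did the shares of cell classes. At 2 or more UMIs the direction turned within retina (1.38% injured against 0% uninjured), while optic nerve had 0.733% against 2.27% (exact permutation p = 1). Without 1 library these were 10.1 to 21.1 points for T-like, -8.54 to -3.55 for oligodendrocyte-like, -21.6 to -2.55 for border macrophage-like and -4.23 to -1.63 for endothelial-like cells. Oligodendrocyte-like cells formed no cluster at resolution 0.3. Where a retina or optic nerve group was left with 1 library, it was assumed to vary like the others. The causes of the moves below were not tested unless the setting itself holds fewer genes or libraries.

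Retina injury (653 genes with edgeR) gave 341 with the DESeq2 Wald test 260 with edgeR on all 8 libraries and 899 with limma on them (623 up and 276 down, against 331 and 322). Without 1 library it gave 415 (without injured pool 3 and 4) to 699, with 428 without pool 1 and 2.

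Optic nerve injury (30 genes with limma) gave 62 and 99 on unlogged means with pseudocounts of 0.1 and 1, 1 with all genes with a UMI in both tissues (826 at an unadjusted p under 0.05), and 0 with all genes with at least 1 count (1243 unadjusted). It gave 50 with at least 30 cells per library, 53 with edgeR, 55 with edgeR and DESeq2 size factors, 71 with DESeq2, 16 with edgeR without other cell types, and 1 on thinned cells. Without 1 library it gave 7 (without uninjured library 2) to 67 (without injured library 1), with 13 without injured library 3.

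The interaction (297 genes) gave 28 with all genes with a UMI in both tissues, 0 with all genes with at least 1 count (2577 unadjusted), 173 with at least 30 cells, 72 with edgeR, 69 with DESeq2 size factors, 112 with DESeq2, 182 without other cell types, 48 with edgeR without them, 154 on cells with at least 1000 UMIs, and 31 on these cells thinned. Without 1 library it gave 86 (without injured optic nerve 3) to 541 (without uninjured retina 5), with 106 and 157 without the injured retina pools 3 and 4, and 1 and 2, 118 and 154 without uninjured optic nerve 4 and 2, and 165 without injured optic nerve 1. Lower calls were 69.7% with limma, 51.4% with edgeR and 22.6% on thinned cells.

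Uninjured tissues (531 genes) gave 260 with only the groups compared, 238 with at least 30 cells, 120 with edgeR, 124 with DESeq2 size factors, 152 with DESeq2, 52 with edgeR without other cell types, and 102 on thinned cells. Without 1 library they gave 227 (without uninjured optic nerve 2) to 907 (without uninjured retina 5), with 242 without uninjured optic nerve 4 and 351 without uninjured retina 6. Lower calls were 82.3% with limma, 53.3% with edgeR and 75.5% on thinned cells.

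Injured tissues (713 genes) gave 172 and 249 on unlogged means with pseudocounts of 0.1 and 1, 440 with all genes with a UMI in both tissues, 354 with all genes with at least 1 count, 1168 with only the groups compared, 1245 with at least 30 cells, 383 with edgeR, 380 with DESeq2 size factors, 272 with DESeq2, 243 with edgeR without other cell types, 182 on cells with at least 1000 UMIs, and 26 on these cells thinned. Without 1 library they gave 143 (without injured optic nerve 3) to 1085 (without uninjured retina 5), with 197 and 290 without the injured retina pools 1 and 2, and 3 and 4, and 220 without injured optic nerve 1. Against limma, edgeR gave the opposite sign for 4 of 701 calls here, 4 of 530 between uninjured tissues and 2 of 295 in the interaction. No paired analysis was possible because each injured retina pool carries 2 sample numbers.

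Rbpms-positive against Rbpms-negative cells (2 genes) gave 0 without the replicate block (53 unadjusted), 0 with negative cells matched on depth (130), 0 on unlogged means with pseudocounts of 0.1 (308) and 1 (269), and 0 with all genes with a UMI in both tissues (332). The counts were 56 with edgeR, 57 with DESeq2 size factors, 13 with DESeq2, 12 with edgeR and matched depth, 1 without other cell types, 3 without them at matched depth, 18 with edgeR without them, 1 without overlapping genes, and 1 without any 1 library. The fits without other cell types held only injured retina pool 1 and 2 and injured optic nerve library 3. Malat1 turned to -0.13 with edgeR, -0.0077 with DESeq2 size factors and -0.0063 with DESeq2, and Gpm6b to 0.066 without other cell types at matched depth. Classes with at least 2 UMIs gave no value, since 1 library had enough cells. Fits of only microglia-like or macrophage-like clusters gave none, since they held too few cells in injured retina and optic nerve libraries.

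Gene lists passing by camera were 7 in retina, 11 in optic nerve, 14 in the interaction, 12 and 12 between uninjured and injured tissues and 3 for Rbpms. With an estimated correlation 0 passed in each, and with fry 4, 2, 0, 8, 4 and 0. Among genes named for retina, Fn1 alone lost its call in 1 setting (0.68, limma adjusted p = 0.093, on all 8 libraries). Values of named genes that passed and that no longer passed in alternatives numbered 236 and 174 for optic nerve injury, 437 and 86 for the interaction, 517 and 34 for uninjured and 505 and 42 for injured tissues. For the Rbpms classes 81 values stayed on their side of the threshold, 20 lost and 3 gained a call, and 4 turned sign.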

Other observations

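No test in this part was planned. Among 117 cells of a cluster seen in injured retina alone (77.1% and 57.9% of the pools), the proton pump gene Atp6v0c, Rnasek and the heat shock genes Hsph1 and Hspa1b led, and no list of cell-type markers named it, while Hsph1, Hspa1b, Bag3, Hspa1a, Hsp90aa1 and Dnajb1 of its 10 leading genes are on the heat shock list. In uninjured retina Atp6v0c had 3 UMIs, and Rnasek and Nme2, also among its 10 leading genes, had 0, so that a difference in annotation or merging between the retina groups was not separated from injury for this cluster. Averaged over tissues its share differed by 33.7 points between injured and uninjured libraries (exact permutation p = 0.333, the smallest possible with 0 such cells in optic nerve). A cluster of 188 cells was led by Il6st, Col27a1 and P2ry12, with Ccl3, Sbno2, Gpr84 and Casp4 also among its 10 leading genes. It held 83.9% and 100% of the uninjured retina libraries and 0.917% and 0% of the injured pools. In optic nerve it made up 19.4% and 53.6% of uninjured libraries 2 and 4 and 17.8% and 12.9% of injured libraries 1 and 3. Its mean share went from 91.9% in uninjured to 0.459% in injured retina and from 36.5% to 15.4% in optic nerve, an average over the tissues of -56.3 points (exact permutation p = 0.0556, the smallest possible). In retina the same difference in annotation or merging was not separated from injury for it. A cluster of 202 cells led by Gpnmb, Apoc1, Lyz2 and Spp1, genes of lipid-laden macrophages, made up 28.6% of injured optic nerve library 3 and 1.37% of injured library 1. It held a median of 20721.5 UMIs per cell, and its share differed by 6.66 points averaged over tissues (exact permutation p = 0.722). A cluster of 449 cells with a median of 956 UMIs made up 66.4% and 48.5% of the injured optic nerve libraries 1 and 3 and 12.6% and 28.6% of the uninjured libraries 2 and 4. Averaged over tissues its share differed by 18.4 points (exact permutation p = 0.333, the smallest possible with 0 such cells in retina).

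At a finer resolution, 72 cells formed a cluster led by the proliferation gene Mki67, of which 71 were in injured optic nerve library 3. Their median depth was 26209.5 UMIs. At that resolution 65 cells, led by P2ry12 and Ccl3 with Tmem119, were named homeostatic microglia-like, 25 and 12 of them in uninjured retina libraries 5 and 6 and 17 and 11 in uninjured optic nerve libraries 2 and 4. None lay in an injured library. An unnamed cluster of 120 cells at that resolution was led by Gpr84 and Sbno2. It held 27 and 89 cells in injured optic nerve libraries 1 and 3, 1 and 2 in uninjured optic nerve libraries 2 and 4, and 1 in injured retina pool 1 and 2.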
